A study of Homo sapiens with 9 samples.

How the data were processed

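Poly(A)-selected messenger RNA was measured in 9 libraries of human endometriotic stromal cells grown from an ovarian endometrioma. Per the labels, the cells were starved overnight in medium with 2% charcoal-stripped fetal bovine serum, pretreated for 30 minutes and then treated for 6 hours. The 3 groups of 3 libraries received vehicle (DMSO), interleukin 1 beta (IL1beta) at 10 ng/ml, or IL1beta at the same dose with 1 µM CDD-2728, which the labels describe as an inhibitor of the kinase JNK. CDD-2728 without IL1beta was not analysed here. The labels do not state whether replicates were separate cultures or came from different donors, so p-values measure the spread between these libraries, which may be technical. All 9 library names begin with the same prefix, whose meaning is not stated, so the cells may come from a single donor.

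The deposited values were raw counts of reads per Ensembl gene. They were whole numbers with no normalization, made by the authors with fastp, HISAT2 and featureCounts on the hg38 genome build, per the labels. The versions of these tools, the strand setting and the annotation release are not given in the sources used here. With the strand setting unknown, reads from overlapping genes on the opposite strand could not be separated. Overlaps are given below for only some genes. Others share exon bases too, on either strand: HOXA10 976, ACTA2 896, ICAM1 876, THBS1 859, IL6 474 and IFIT2 421. The table held 62750 genes. Of its gene IDs, 62672 matched a symbol table and 78 did not. Gene positions and exon lengths came from GENCODE release 29 on GRCh38, and 16450 of the tested genes had an exon length there.

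Counts per library ranged from 33402733 to 47721630. Genes were kept with the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 17001 genes holding 99.9% of all counts. Libraries were scaled by the trimmed mean of M values (TMM). All 9 libraries entered 1 model with a mean per group (limma 3.58.1 supplied shared routines), and each of 3 comparisons was tested with edgeR's robust quasi-likelihood F test, which is two-sided. The common dispersion was 0.0112. P-values were adjusted by the Benjamini-Hochberg method over all tested genes within a comparison, and an adjusted p under 0.05 was called. Fold changes are on the log2 scale with a prior count of 0.125, and SE is the standard error of the fitted log2 fold change. Expression is given as TMM-scaled CPM (the count of a gene relative to the scaled library total), mean ± SD of 3 libraries. For a gene with 0 counts in all vehicle libraries, the fold was computed against a floor of 3 counts over the group and is written as a lower bound. With 1 to 3 vehicle counts, the ratio is given with its 95% counting interval. Floors and intervals cover counting error only. No replicate pairing was used, since the labels state none.

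Gene lists were written before the data were examined, as were the main test, its threshold and the comparisons. They comprised 18 pathway lists and 7 cell marker lists with 490 symbols in all. The pathway lists covered cytokines and chemokines, NF-kB feedback and subunits, AP-1 and immediate-early genes, MAPK phosphatases and feedback, JNK cascade components, matrix proteases and inhibitors, the prostaglandin pathway, steroid synthesis and hormone receptors, the type I interferon response, extracellular matrix and contractile genes, decidualization and endometrial stromal regulators, adhesion with growth factors and angiogenesis, apoptosis and survival, the cell cycle, oxidative stress and metallothioneins, the unfolded protein and integrated stress response, mRNA decay and cytokine signalling feedback, and complement and acute-phase genes. The marker lists covered stromal fibroblasts, epithelium, macrophages and leukocytes, endothelium, mesothelium, granulosa and ovarian stroma, and smooth muscle and pericytes. Each list with at least 5 tested members was compared with all other genes by camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Members called are counted with the adjustment over all genes, and also adjusted over the list alone.

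The genes named were chosen by a rule. For IL1beta against vehicle, and for CDD-2728 with IL1beta against IL1beta, it took the 10 largest increases and 10 largest decreases among genes with an adjusted p under 0.05, no overlap between the libraries of both groups, a mean of at least 5 CPM in the higher group and a symbol. Y-linked genes and XIST were left out. For CDD-2728 with IL1beta against vehicle it took 5 and 5. Of the genes raised at least 2-fold by IL1beta (at least 5 CPM), it added the 6 lowered most by CDD-2728 and the 6 with the largest IL1beta increase that were not called for CDD-2728. From each list and comparison it added up to 4 called members with the largest change (at least 1 CPM) and up to 2 members not called with the highest expression. CXCL8, IL6, CCL2, PTGS2, MMP1, MMP3, ICAM1, NFKBIA, TNFAIP3, JUN, FOS, FOSL1, ATF3, DUSP1, MAPK8 and MAPK9 were always included. The text gives a selection of these genes. 1 gene is not reported here.

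The method was tested on simulated data made from these libraries. Changes of 1.5-fold, 2-fold and 4-fold were recovered for 55.2%, 59.7% and 80.3% of altered genes in the vehicle and IL1beta libraries, where 8 of 138 calls were false. In the IL1beta libraries with and without CDD-2728 the values were 49.3%, 73.1% and 89.4%, with 7 of 148 calls false. Of 10 lists raised 1.3-fold, 10 were called, against 1 of 219 unaltered lists. The simulated genes varied independently of each other, so this does not give the rate of false list calls among correlated genes. All libraries were drawn with the same dispersion per gene. None thus stood apart from its group as CDD-2728 library 1 did in the data, and the rates do not cover such a library. Counts simulated with no effect of CDD-2728 (20 draws) gave the values expected from IL1beta libraries that enter both comparisons.

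Alternatives chosen in advance were DESeq2 size factors, library size only or upper-quartile scaling; no low-count filter, or at least 1 CPM in 3 libraries; DESeq2 1.42.0 or limma-voom; only the 2 groups compared; a block for replicate number; an adjusted p under 0.01; a test against a fold of 1.2 (glmTreat); each library left out in turn; camera with estimated correlation or with the block, and fry; and a minimum IL1beta change of 2 on the log2 scale, or none. Removal of each library's trend on exon length, its partner fit over genes with an exon length, removal of mitochondrially encoded genes, and a mean CPM scale were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.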

Results

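Messenger RNA was counted in 9 libraries of human endometriotic stromal cells, fibroblast-like cells grown from an ovarian cyst lined by endometrium-like tissue. The 3 groups of 3 libraries were treated for 6 hours with vehicle, with the inflammatory cytokine IL1beta, or with IL1beta and CDD-2728, an inhibitor of the stress-activated kinase JNK. Total counts were 47721630, 42255671 and 43552243 in vehicle libraries 1 to 3. They were 43649313, 39599852 and 37208804 in the IL1beta libraries, and 33402733, 45547461 and 38316987 in the libraries with CDD-2728. The first principal component of the tested genes held 56.3% of the variance and the second 9.08%. On the second component, library 1 of the CDD-2728 group lay at 57.6 and the other 8 libraries lay between -21.1 and 2.29. Mitochondrially encoded genes took 1.76% ± 0.0723 of counts with vehicle, 2.09% ± 0.190 with IL1beta and 2.36% ± 0.189 with CDD-2728 (SD, n = 3 each).

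The comparison of IL1beta with vehicle asked which genes the cytokine changes in these cells. The neutrophil-attracting chemokine CXCL8 (ENSG00000169429.12, GRCh38 chromosome 4, 73740506 to 73743716) rose from 1.19 ± 0.974 to 11018 ± 437 CPM, a log2 fold change of 13.20 (SE 0.39, adjusted p = 9.4e-08). Its vehicle libraries were at 0.685, 2.309 and 0.566 CPM, so the size of this fold depends on vehicle library 2. The cytokine gene IL6 (ENSG00000136244.12, chromosome 7, 22725884 to 22732002) rose 139-fold, from 3.69 ± 0.204 to 512 ± 26.4 CPM (log2 7.12, SE 0.075, adjusted p = 1e-19). The leukocyte adhesion receptor ICAM1 (ENSG00000090339.9, chromosome 19, 10270835 to 10286615) rose 59.6-fold to 1733 ± 19.7 CPM (log2 5.90, SE 0.069). Among decreases, the stem cell factor receptor KIT (ENSG00000157404.17, chromosome 4, 54657918 to 54740715) went from 7.88 ± 2.09 to 0.563 ± 0.131 CPM, a log2 change of -3.80 (SE 0.40, adjusted p = 6.4e-07). For each of these genes, all 3 IL1beta libraries lay beyond all 3 vehicle libraries. Tests were edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

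All 27 tested members of the list of cytokines and chemokines were called higher (camera adjusted p = 6.8e-251), and 27 were higher adjusted over the list alone. With genes that had no vehicle counts set at their bound, the list's median log2 fold change was 7.13. The chemokines CXCL1 and CXCL2 rose by 14.67 (SE 0.61) and 13.78 (SE 0.75) on the log2 scale, to 1200 ± 53.4 and 646 ± 18.2 CPM. In vehicle, CXCL2 was counted only in library 2 (0.136 CPM) and CXCL1 was at 0.081, 0.045 and 0 CPM. The sizes of both folds thus rest on few counts. The monocyte chemokine CCL2 rose 96.0-fold to 179 ± 7.37 CPM (adjusted p = 7.5e-19). No vehicle library had a count of CSF3, the granulocyte growth factor, which was at least 24755-fold higher with IL1beta. By the same measure CXCL3 was at least 11171-fold, CXCL5 at least 2542-fold and CCL5 at least 762-fold higher. CCL20, with 2 vehicle counts, had a ratio of 5385 (95% counting interval 1490 to 44470). CXCL1, CXCL2 and CXCL3 are similar in sequence, and reads shared between them could not be told apart.

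Of 25 NF-kB feedback and subunit genes, 25 were called higher, and 25 adjusted over the list alone (camera adjusted p = 7.9e-168, median log2 3.19). The weakest, TNIP2 (log2 0.27, adjusted p = 0.044), lost its call with library size only (log2 0.22) and with upper-quartile scaling (log2 0.14). It also lost it without vehicle library 1 (adjusted p = 0.19), 2 (0.072) or 3 (0.056), IL1beta library 2 (0.22) or 3 (0.077), or CDD-2728 library 3 (0.057). The NF-kB inhibitors TNFAIP3 and NFKBIA rose 67.4-fold (log2 6.07, SE 0.080) and 17-fold (log2 4.09, SE 0.094). The survival factor BIRC3 rose by 9.08 (SE 0.23), the signalling adaptor TRAF1 by 6.60 (SE 0.13) and TNFAIP2 by 5.95 (SE 0.060) on the log2 scale. In the adhesion, growth factor and angiogenesis list 18 members were higher, 4 lower and 5 not called (19 and 4 adjusted over the list alone; camera adjusted p = 2.4e-23). VCAM1 rose from 0.820 ± 0.664 to 85.0 ± 1.94 CPM, and the endothelial-type adhesion gene SELE was at least 334-fold higher. Among complement and acute-phase genes, 8 were higher, 0 lower and 7 not called (8 and 0 adjusted over the list alone; camera adjusted p = 2.0e-08), with PTX3 at log2 5.49 (SE 0.061) and C3 at 4.27 (SE 0.13). Among oxidative stress and metallothionein genes, 10 were higher, 0 lower and 8 not called (10 and 0 adjusted over the list alone; camera adjusted p = 9.7e-13). The mitochondrial superoxide dismutase SOD2 rose 72.5-fold to 9024 ± 69.6 CPM and the zinc importer SLC39A14 by 3.53 (SE 0.050) on the log2 scale.

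The AP-1 and immediate-early list had 11 members higher, 4 lower and 9 not called (11 and 4 adjusted over the list alone). Its camera adjusted p was 3.5e-05, or adjusted p = 0.067 with an estimated correlation. JUN, an AP-1 subunit and JNK substrate (ENSG00000177606.8, chromosome 1, 58780788 to 58784327), rose from 230 ± 16.1 to 741 ± 38.1 CPM, a log2 change of 1.68 (SE 0.073, adjusted p = 7.2e-12). ATF3 rose by 3.36 (SE 0.11), the nuclear receptor NR4A3 by 4.64 (SE 0.092) and FOSL1 by 0.56 (SE 0.064), while MYC changed by -0.69 (SE 0.098). FOS was low in both groups (1.5 ± 0.459 and 0.658 ± 0.209 CPM). Its log2 change of -1.19 (SE 0.37, adjusted p = 0.021) lost its call without vehicle library 1 (adjusted p = 0.051), vehicle library 3 (0.11) or IL1beta library 1 (0.097). Of the MAPK phosphatases and feedback genes, 9 were higher, 5 lower and 5 not called (9 and 6 adjusted over the list alone; camera adjusted p = 0.21). DUSP8, a phosphatase acting on JNK and p38, rose 4.02-fold from 6.09 ± 0.780 to 24.5 ± 2.20 CPM. DUSP1 was not called (log2 -0.16, adjusted p = 0.052), but it was without CDD-2728 library 1 (adjusted p = 0.0014), 2 (0.048) or 3 (0.047). Of the JNK cascade components, 9 were higher, 1 lower and 11 not called (9 and 1 adjusted over the list alone; camera adjusted p = 0.019, or 0.071 with an estimated correlation). Without vehicle library 2 only 4 were higher. The kinases MAP3K8 and MAP3K5 rose by 3.70 (SE 0.15) and 2.32 (SE 0.072), and the JNK genes MAPK8 and MAPK9 were not called (log2 0.07 and -0.11).

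Matrix proteases and inhibitors had 13 members higher, 5 lower and 4 not called (14 and 5 adjusted over the list alone; camera adjusted p = 2.0e-09). The stromelysin MMP3 (ENSG00000149968.12, chromosome 11, 102835801 to 102843803) rose 3.73-fold to 1182 ± 85.7 CPM. The collagenase MMP1 (ENSG00000196611.6, chromosome 11, 102789920 to 102798160) rose 3.80-fold to 109 ± 12.6 CPM. The protease inhibitor SERPINB2 rose 21.5-fold to 1127 ± 53.3 CPM, and shares 547 exon bases with SERPINB10 on the same strand. In the prostaglandin list 6 members were higher, 5 lower and 8 not called (6 and 6 adjusted over the list alone). Its median log2 fold change was -0.04 while its mean was 0.82, and camera called it higher (adjusted p = 0.0021). PTGS2, which encodes the inducible cyclooxygenase, rose from 0.174 ± 0.181 to 41.0 ± 2.96 CPM, and the prostaglandin E synthase PTGES rose by 3.12 (SE 0.099). In the type I interferon list 24 were higher, 0 lower and 7 not called (26 and 0 adjusted over the list alone; camera adjusted p = 1.9e-25, median log2 1.83). GBP2 rose by 4.23 (SE 0.072) and IFIT2 by 1.07 (SE 0.10), while IFIT1 was not called (log2 -0.05, adjusted p = 0.77). The extracellular matrix and contractile list had 2 members higher, 11 lower and 17 not called (2 and 11 adjusted over the list alone; camera adjusted p = 0.18, or 0.0033 without the low-count filter). With library size only 19 were lower, and with upper-quartile scaling 17. The matricellular gene THBS1 changed by -1.09 (SE 0.057), from 8753 ± 554 to 4104 ± 49.4 CPM, while tenascin (TNC) rose by 2.74 (SE 0.059).

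Apoptosis and survival genes had 12 members higher, 3 lower and 7 not called (13 and 5 adjusted over the list alone; camera adjusted p = 0.00021). With CDD-2728 library 1 left out, 5 were lower. BCL2A1, an inhibitor of cell death, was at least 583-fold higher, and the cell death activator BMF changed by -2.76 (SE 0.18). For mRNA decay and cytokine signalling feedback, 12 were higher, 4 lower and 3 not called (13 and 4 adjusted over the list alone; camera adjusted p = 0.0044), with SOCS3 at log2 1.94 (SE 0.11). The unfolded protein and integrated stress response list had 9 higher, 3 lower and 7 not called (10 and 3 adjusted over the list alone). Its camera adjusted p was 0.00013, or 0.067 with an estimated correlation. Without vehicle library 2 or IL1beta library 1, 2 or 3, 1 member was lower. Among decreases, NR2F2, a regulator of endometrial stromal differentiation (ENSG00000185551.15, chromosome 15, 96325938 to 96340263), went from 937 ± 5.25 to 248 ± 4.91 CPM (log2 -1.92, SE 0.055, adjusted p = 2.1e-14). SOX9 went from 21.7 ± 1.38 to 2.88 ± 0.479 CPM (log2 -2.91, SE 0.16). The phosphodiesterase PDE7B changed by -3.83 (SE 0.35) and the hair keratin-associated gene KRTAP1-5, which has close paralogs, by -3.56 (SE 0.093).

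In all, 2677 genes were higher with IL1beta and 2309 lower, of which 984 and 480 changed at least 2-fold. With each library left out in turn, 2183 to 3286 were higher and 1721 to 3113 lower. Both highest counts came without CDD-2728 library 1 (6399 genes called, against 4986 with all libraries). That library is in neither group compared and enters only through the shared model. Library-size scaling shifted the median log2 fold change of all genes to -0.11, from -0.01 with TMM. With it the higher share of called genes was 36.2% in place of 53.7%, and with upper-quartile scaling 41.0%, so that the smaller changes here are relative to the TMM scale.

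**Figure D1:**
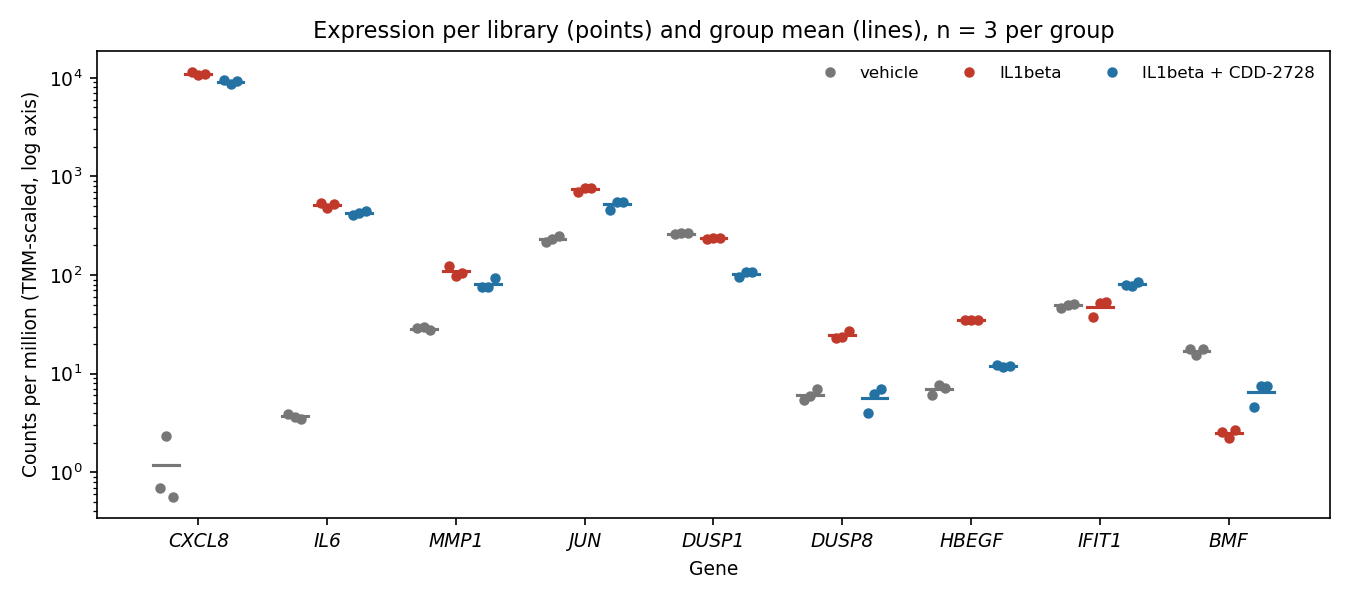
TMM-scaled CPM on a log axis for 9 genes in each library, with n = 3 libraries per group as points and group means as lines. CXCL8 and IL6 are high in both IL1beta groups, whereas DUSP8, DUSP1 and HBEGF are lower with CDD-2728 than with IL1beta alone, and BMF and IFIT1 higher.

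The comparison of CDD-2728 with IL1beta against IL1beta alone asked which genes the JNK inhibitor changes in cytokine-treated cells. DUSP8 (ENSG00000184545.11, chromosome 11, 1554044 to 1571920) was 4.28-fold lower, at 5.68 ± 1.54 CPM (log2 -2.10, SE 0.16, adjusted p = 9.6e-07). CREB5, a transcription factor gene (ENSG00000146592.17, chromosome 7, 28299321 to 28825894), was 4.27-fold lower, from 14.3 ± 0.719 to 3.38 ± 0.852 CPM (log2 -2.09, SE 0.16, adjusted p = 9.6e-07). The epidermal growth factor receptor ligand HBEGF (ENSG00000113070.8, chromosome 5, 140332843 to 140346631) was 2.93-fold lower, from 35.0 ± 0.354 to 11.9 ± 0.277 CPM (log2 -1.55, SE 0.10, adjusted p = 1.3e-07). In the other direction, BMF (ENSG00000104081.14, chromosome 15, 40087890 to 40108892) was 2.64-fold higher, from 2.49 ± 0.233 to 6.55 ± 1.66 CPM (log2 1.40, SE 0.18, adjusted p = 2.3e-04). For these genes the 3 libraries with CDD-2728 lay beyond the 3 with IL1beta alone, and BMF shares 461 exon bases with BMF-AS1 on the other strand. Tests were edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With CDD-2728, DUSP8 and CREB5 were not called against vehicle (log2 -0.09 and 0.04, adjusted p = 0.76 and 0.90), which does not show that they equalled it.

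Of the MAPK phosphatases and feedback genes, 8 were lower with CDD-2728, 0 higher and 11 not called (8 and 1 adjusted over the list alone; camera adjusted p = 1.2e-27). In fits that left out 1 library, 6 to 8 were lower, and 1 was higher without CDD-2728 library 1 or 3. The general MAPK phosphatase DUSP1 (ENSG00000120129.6, chromosome 5, 172768090 to 172771195) went from 235 ± 2.29 to 103 ± 6.99 CPM (log2 -1.18, SE 0.060, adjusted p = 1.3e-08). The receptor signalling inhibitor SPRY2 and the stress gene GADD45A each changed by -1.01 (SE 0.079 and 0.089). The AP-1 and immediate-early list had 8 members lower, 0 higher and 16 not called (12 and 0 adjusted over the list alone; camera adjusted p = 1.5e-14, median log2 -0.22). JUN went from 741 ± 38.1 to 520 ± 52.3 CPM (log2 -0.51, SE 0.073, adjusted p = 6.0e-04) and FOSL1 from 113 ± 0.766 to 88.9 ± 4.81 CPM (log2 -0.35, SE 0.064). JUND and EGR1 changed by -0.84 (SE 0.076 and 0.15), KLF6 by -0.83 (SE 0.053) and MYC by -0.60 (SE 0.10). ATF3 was not called (log2 -0.35, adjusted p = 0.067), but it was without vehicle library 1 (adjusted p = 0.031) or CDD-2728 library 1 (0.024). FOS was not called (log2 0.68, adjusted p = 0.52). Of the JNK cascade components 1 was lower and 20 were not called (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.91). The 1 lower was MAP3K4 (log2 -0.34), whose call was lost when any library but CDD-2728 library 1 was left out (adjusted p = 0.068 to 0.19). Without CDD-2728 library 1, MAPK8 was called lower (log2 -0.21, adjusted p = 0.011, against 0.55 with all libraries), and 3 members were lower and 2 higher. MAPK9 was not called (log2 0.00).

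Matrix proteases and inhibitors had 11 members lower, 0 higher and 11 not called (12 and 0 adjusted over the list alone; camera adjusted p = 3.1e-19, median log2 -0.31). The macrophage-type elastase MMP12 (ENSG00000262406.3, chromosome 11, 102862736 to 102875034) was 2.93-fold lower at 4.94 ± 0.615 CPM (log2 -1.55, SE 0.19, adjusted p = 1.5e-04). SERPINB2 changed by -0.82 (SE 0.070) and MMP10 by -0.57 (SE 0.088). MMP3 went from 1182 ± 85.7 to 915 ± 70.3 CPM (log2 -0.37, SE 0.065, adjusted p = 0.0031). MMP1 went from 109 ± 12.6 to 81.9 ± 10.6 CPM (log2 -0.41, SE 0.093, adjusted p = 0.022). Its call was lost without vehicle library 2 (adjusted p = 0.053), IL1beta library 1 (0.18) or 3 (0.070), or CDD-2728 library 2 (0.088). In the adhesion, growth factor and angiogenesis list 5 members were lower, 2 higher and 20 not called (8 and 4 adjusted over the list alone; camera adjusted p = 7.9e-09). With CDD-2728 library 1 left out, 11 were lower and 4 higher, and 1 was higher without vehicle library 1 or 3, any 1 IL1beta library, or CDD-2728 library 3. The growth factor NRG1 changed by -1.01 (SE 0.082), from 201 ± 12.5 to 99.8 ± 5.79 CPM. TNC changed by -1.02 (SE 0.058), from 641 ± 10.1 to 316 ± 20.9 CPM, and shares 129 exon bases with another gene.

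Cytokines and chemokines split, with 9 members lower, 2 higher and 16 not called (12 and 5 adjusted over the list alone). The camera adjusted p was 1.3e-04, or adjusted p = 0.23 with an estimated correlation. Without IL1beta library 1, 2 or 3, 5, 5 and 4 members were lower, and without CDD-2728 library 1, 6 were higher. Without IL1beta library 1 or 2, or CDD-2728 library 2 or 3, 1 was higher. The interleukin 6 family cytokine LIF went from 481 ± 34.4 to 237 ± 32.8 CPM (log2 -1.02, SE 0.096, adjusted p = 7.8e-06). The epithelial-type alarmin TSLP went from 19.0 ± 1.57 to 8.26 ± 0.689 CPM (log2 -1.21, SE 0.17, adjusted p = 6.3e-04), and CSF3 changed by -0.41 (SE 0.067). CXCL6 was higher, from 134 ± 7.45 to 199.6 ± 29.3 CPM (log2 0.58, SE 0.089, adjusted p = 0.0011). IL6 went from 512 ± 26.4 to 424 ± 19.3 CPM (log2 -0.27, SE 0.059, adjusted p = 0.016), a call lost without vehicle library 2 (adjusted p = 0.051) or IL1beta library 1 (0.12) or 3 (0.10), and in a fit of only these groups (0.061). CXCL8, at 9133 ± 487 CPM, was not called (log2 -0.27, SE 0.22, adjusted p = 0.74). Yet its libraries did not overlap, at 8577 to 9482 CPM with CDD-2728 and 10584 to 11458 with IL1beta alone. The fit shares its spread with the vehicle libraries, where CXCL8 was at 0.685, 2.309 and 0.566 CPM. The missing call therefore does not show that CXCL8 was unaffected. CXCL8 was called without vehicle library 2 (adjusted p = 0.021), by limma-voom (0.0035) and in a fit of only these groups (0.026). CCL2 (log2 0.11, adjusted p = 0.52) and CCL5 (log2 0.19, adjusted p = 0.61) were not called. CXCL1 (log2 0.16, adjusted p = 0.48) and CXCL2 (log2 -0.35, adjusted p = 0.090) were not called with all libraries, but both were without CDD-2728 library 1 (adjusted p = 2.6e-04 and 0.018). CXCL2 was also called without vehicle library 2 (adjusted p = 0.032), by DESeq2 (0.0020) and by limma-voom.

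The NF-kB list had 7 members lower, 1 higher and 17 not called (7 and 1 adjusted over the list alone; camera adjusted p = 0.0035, or 0.083 with an estimated correlation). Without vehicle library 2 or 3, IL1beta library 1, 2 or 3, or CDD-2728 library 3, the lower members numbered 3, 4, 4, 3, 3 and 4. Without CDD-2728 library 1, 3 were higher. TRAF1 changed by -0.83 (SE 0.095), from 215 ± 8.74 to 121 ± 6.55 CPM, and TNFAIP6 by 0.40 (SE 0.060). TNFAIP3 changed by -0.30 (SE 0.074, adjusted p = 0.037), a call lost without vehicle library 2 (adjusted p = 0.083), IL1beta library 1 (0.14), 2 (0.16) or 3 (0.18), or CDD-2728 library 3 (0.14). NFKBIA (log2 -0.20, adjusted p = 0.34) and ICAM1 (log2 -0.09, adjusted p = 0.68) were not called. Of 19 prostaglandin pathway members, 0 were called by edgeR (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.28), 2 by DESeq2 and 0 by limma-voom, and 6 had an unadjusted p under 0.05. PTGS2, at 40.0 ± 3.94 CPM (log2 -0.04, SE 0.15), and PTGES (log2 0.06, SE 0.090) were not called. With CDD-2728 library 1 left out, 3 were higher and 1 lower, and 1 was higher without vehicle library 3 or CDD-2728 library 3. For mRNA decay and cytokine signalling feedback, 3 were lower, 1 higher and 15 not called (6 and 1 adjusted over the list alone; camera adjusted p = 1.8e-04), with SOCS3 at log2 -0.68 (SE 0.11). Without CDD-2728 library 1, 8 were lower, and without any 1 of the other 8 libraries 0 were higher.

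Interferon-response genes were higher with CDD-2728 than with IL1beta alone, with 10 of 31 members higher, 0 lower and 21 not called (17 and 0 adjusted over the list alone; camera adjusted p = 9.8e-22, median log2 0.40). IFIT2 (ENSG00000119922.11, chromosome 10, 89283694 to 89309276) went from 47.1 ± 7.63 to 90.1 ± 2.48 CPM (log2 0.94, SE 0.10, adjusted p = 3.2e-05). IFIT1 (ENSG00000185745.10, chromosome 10, 89392546 to 89406486) went from 47.5 ± 8.90 to 80.2 ± 3.57 CPM (log2 0.76, SE 0.10, adjusted p = 4.7e-04). These are members of a family of similar genes. The number of members called was 3 without IL1beta library 1, 5 without IL1beta library 2, 6 without CDD-2728 library 3 and 16 without CDD-2728 library 1. RSAD2, from 5.86 ± 2.07 to 11.5 ± 1.63 CPM (log2 0.97, adjusted p = 0.024), lost its call without IL1beta library 1 (adjusted p = 0.13) or 3 (0.14) or CDD-2728 library 3 (0.073). Of the 176 genes higher with CDD-2728, IL1beta had lowered 78, raised 56 and left 42 not called. The deubiquitinase STAMBPL1 (ENSG00000138134.12, chromosome 10, 88879734 to 88975153) was 2.07-fold higher, from 23.7 ± 1.07 to 49.0 ± 3.92 CPM (log2 1.05, SE 0.080, adjusted p = 9.6e-07), against 43.1 ± 0.555 with vehicle. The adhesion gene PCDH18 changed by 0.97 (SE 0.081), from 60.0 ± 4.56 to 117 ± 11.5 CPM. THBS1 changed by 0.71 (SE 0.057), from 4104 ± 49.4 to 6694 ± 552 CPM, and smooth muscle actin (ACTA2) by 0.49 (SE 0.069). METTL7A, not called with IL1beta alone (log2 -0.17, adjusted p = 0.67), was 3.05-fold higher at 5.30 ± 0.827 CPM (log2 1.61, SE 0.24). The extracellular matrix and contractile list had 3 members higher, 1 lower and 26 not called (6 and 2 adjusted over the list alone; camera adjusted p = 0.056). Among other fits, it was called without vehicle library 2 (adjusted p = 0.042) or 3 (0.041), IL1beta library 2 (0.039), or CDD-2728 library 1 (0.0025) or 3 (0.027), with library size only (0.041) and with upper-quartile scaling (0.026). No low-count filter (adjusted p = 0.011), the exon length trend removed (0.022) and no mitochondrially encoded genes (0.044) also gave a call. With CDD-2728 library 1 left out, 8 of its members were higher and 2 lower.

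Of the other lists, apoptosis and survival had 2 members higher, 2 lower and 18 not called (3 and 5 adjusted over the list alone; camera adjusted p = 0.39). The number lower was 5 without CDD-2728 library 1, and 1 without vehicle library 2, any 1 IL1beta library or CDD-2728 library 3, while 1 was higher without IL1beta library 2 or 3. Complement and acute-phase genes had 1 higher and 14 not called (1 adjusted over the list alone). Their camera adjusted p of 0.023 was 0.083 with an estimated correlation, and 0.051, 0.080 and 0.078 without IL1beta library 3, CDD-2728 library 2 and CDD-2728 library 3. Its called member, C3 (log2 0.39, adjusted p = 0.038), lost its call without vehicle library 1 (adjusted p = 0.057), IL1beta library 1 (0.14), 2 (0.15) or 3 (0.16), or CDD-2728 library 2 (0.11) or 3 (0.12), and without CDD-2728 library 1, 4 members were called. Oxidative stress genes had 1 lower and 17 not called (1 adjusted over the list alone; camera adjusted p = 0.53). The 1 lower, TXNRD1 (log2 -0.20), was called with all libraries and without CDD-2728 library 1, but not without any other (adjusted p = 0.063 to 0.17), and without CDD-2728 library 1, 4 were lower and 1 higher. The unfolded protein and stress response list had 1 lower and 18 not called (2 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.69). That 1 member, ERN1 (log2 -0.27), lost its call without vehicle library 2 (adjusted p = 0.054), IL1beta library 1 (0.076), 2 (0.11) or 3 (0.10), or CDD-2728 library 3 (0.097), and without CDD-2728 library 1, 2 were lower and 2 higher.

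In all, 176 genes were higher with CDD-2728 and 301 lower, of which 18 and 28 changed at least 2-fold. The numbers changed when libraries were left out, most of all CDD-2728 library 1. With CDD-2728 library 1 left out, 616 were higher (38 at least 2-fold) and 953 lower, and 472 of the 477 genes called with all libraries were among these. Calls for IL1beta against vehicle, which does not compare that library, also rose without it (6399 against 4986). Part of the rise may thus come from the spread that all groups share in the model. Without IL1beta library 1, 2 or 3, 86, 90 and 88 were higher and 171, 139 and 165 lower, and without CDD-2728 library 3, 196 were lower. The drop was similar for each IL1beta library, and these fits have fewer libraries, so it does not single out 1 of them. Of the 79 named genes called in this comparison, 50 kept their call in all 9 fits that left out 1 library. The fit of DESeq2 called 474 of the 477 and limma-voom 455.

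Of the 984 genes that IL1beta raised at least 2-fold, 106 were lowered by CDD-2728 (10.8%, Wilson 95% interval 8.99% to 12.9%) and 33 raised further. The share was 7.21%, 6.18% and 7.0% without IL1beta library 1, 2 and 3, and 15.4% without CDD-2728 library 1. Of the 480 genes that IL1beta lowered at least 2-fold, 39 were raised by CDD-2728 (8.13%, interval 6.00% to 10.9%) and 6 lowered further. This share was 5.0% without IL1beta library 1, 5.39% without IL1beta library 3 and 12.7% without CDD-2728 library 1. Both intervals treat genes as independent draws, which they are not, and leave out the spread between libraries. Both comparisons use the IL1beta libraries. Counts simulated with no effect of CDD-2728 called only 0.5 genes on average in 20 draws, so their mean shares (0% and 0.00693%) and overlaps (0.05 and 0.15 genes) are chance values without an effect and say little about overlaps of longer lists. In 20 further draws the fold changes of genes called with CDD-2728 were given to random genes of similar mean, which gave on average 149 higher and 229 lower genes and shares of 1.11% and 0.719%. Of the 301 genes lowered by CDD-2728, 210 had risen with IL1beta, against 47.4 expected of independent lists and 55.8 (37 to 62) in the draws with effects. Of the 176 raised, 78 had fallen with IL1beta, against 23.9 and 31 (21 to 38). These draws used the IL1beta libraries in both comparisons, as the data do. The observed 210 and 78 lay above their highest values of 62 and 38. This argues against shared libraries as the main source of the excess. The draws had fewer called genes than the data, so the exact part that sharing adds is not known. The median part of the log2 rise left with CDD-2728 was 96.6% (SD 1.82 over 3 libraries; 98.6% in the draws with no effect), and the median part of the fall left was 80.9% (SD 1.00; 93.8% in those draws). Across genes, which are not independent replicates, the fold changes of both comparisons had a Pearson correlation of -0.22 (covariance -0.0953), and the draws with no effect gave -0.15 on average (covariance -0.0518).

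**Figure D2:**
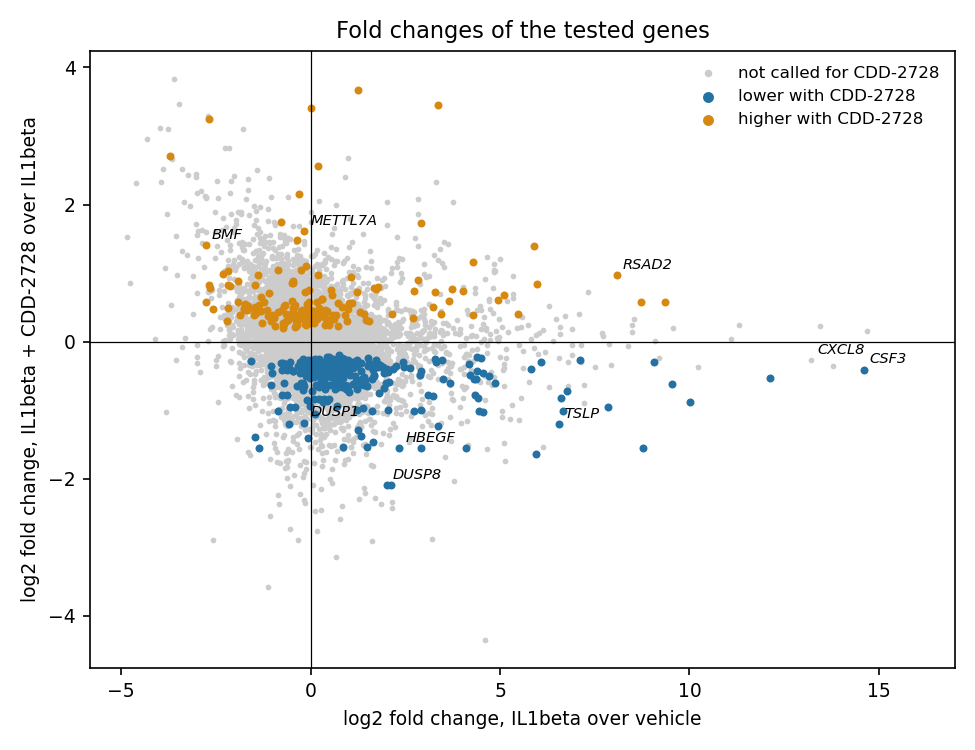
Log2 fold changes of 17000 tested genes for IL1beta over vehicle (x axis) and for IL1beta with CDD-2728 over IL1beta (y axis), with genes called lower for CDD-2728 in blue, higher in orange and not called in grey. Genes with no counts in 1 group are drawn at their bound, and 210 of the 301 lower genes were called higher with IL1beta.

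**Figure D3:**
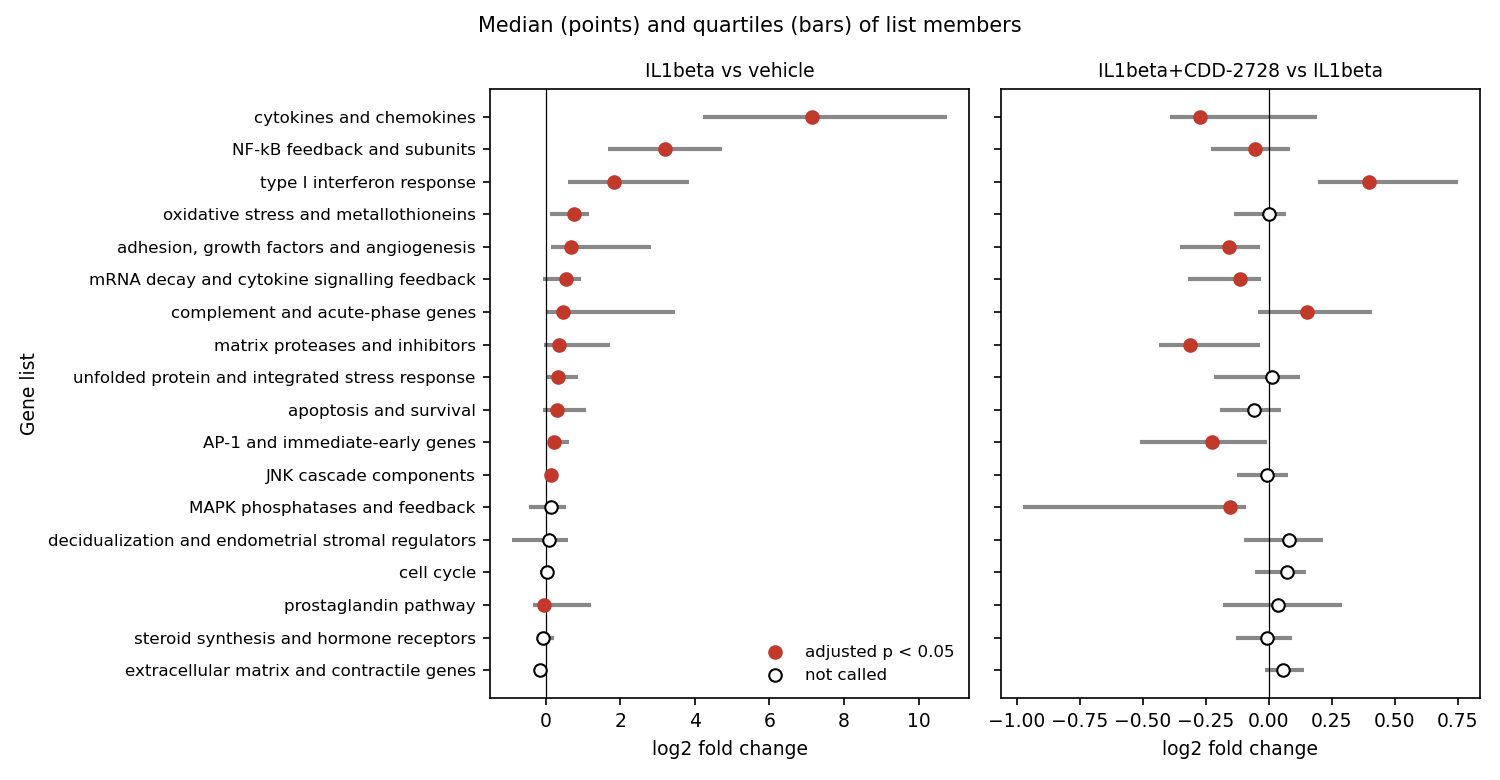
Median log2 fold change (points) with quartiles (bars) of 18 pathway lists for IL1beta over vehicle (left) and for IL1beta with CDD-2728 over IL1beta (right), filled where the camera adjusted p was under 0.05 and with genes with 0 vehicle counts at their bound. The cytokine and NF-kB lists lie highest at left, and at right the interferon list lies above 0 while the AP-1, MAPK phosphatase and matrix protease lists lie below it.

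The comparison of CDD-2728 with IL1beta against vehicle asked what was left of the cytokine response. IL6 was 115-fold higher than with vehicle, at 424 ± 19.3 CPM (log2 6.84, SE 0.075, adjusted p = 1.7e-19), and CXCL8 was at 9133 ± 487 CPM (log2 12.93, SE 0.39, adjusted p = 1.1e-07). CCL2, ICAM1 and PTGS2 had log2 changes of 6.70 (SE 0.092), 5.80 (SE 0.069) and 7.84 (SE 0.45). The largest increases by the naming rule were CSF3 (at least 18824-fold), CXCL3 (at least 13304-fold), CXCL5 (at least 2968-fold), CXCL1 (log2 14.83, SE 0.61) and CXCL2 (log2 13.43, SE 0.75). In vehicle, CXCL2 was counted only in library 2 (0.136 CPM), and CXCL1 reached at most 0.081 CPM. CXCL8 was highest in vehicle library 2 (2.309 CPM). The sizes of these 3 folds thus depend on few vehicle counts or on that library. The largest decreases were KIT at 0.263 ± 0.243 CPM (log2 -4.83, SE 0.48, adjusted p = 1.1e-07), KRTAP1-5 (log2 -3.84, SE 0.095), the serotonin receptor HTR1B (log2 -3.46, SE 0.28), SOX9 (log2 -3.36, SE 0.17) and the caveolar gene CAVIN2 (log2 -3.23, SE 0.25). For each of these genes all 3 libraries of a group lay beyond all 3 of the other, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. MMP3 and MMP1 were 1.53 (SE 0.065) and 1.52 (SE 0.095) above vehicle on the log2 scale, and JUN was 1.18 (SE 0.073) above. DUSP1 lay below vehicle (log2 -1.34, SE 0.060, adjusted p = 9.9e-12), as did MYC (log2 -1.29, SE 0.10), JUND (log2 -0.74, SE 0.076), EGR1 (log2 -0.63, SE 0.15), ADAMTS1 (log2 -0.51, SE 0.057) and KLF6 (log2 -0.48, SE 0.053).

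Cytokines and chemokines again had 27 of 27 members higher (27 adjusted over the list alone; camera adjusted p = 4.3e-253), and the NF-kB list had 24 of 25 higher (25 adjusted over the list alone; camera adjusted p = 2.0e-168). The interferon list had 29 members higher, 0 lower and 2 not called (29 and 0 adjusted over the list alone; camera adjusted p = 4.6e-40, median log2 2.46), with IFIT2 at log2 2.00 (SE 0.10) and IFIT1 at 0.70 (SE 0.10). Matrix proteases had 10 higher, 6 lower and 6 not called (11 and 6 adjusted over the list alone; camera adjusted p = 4.3e-04, or 0.059 with an estimated correlation). The AP-1 list had 7 higher, 8 lower and 9 not called (7 and 8 adjusted over the list alone), with a camera adjusted p of 0.070 that was 0.013 without CDD-2728 library 1. The MAPK phosphatases had 5 higher, 7 lower and 7 not called (5 and 8 adjusted over the list alone; camera adjusted p = 0.070, or 0.033 without the low-count filter). Of these, 3 were higher without vehicle library 1 or 3, or CDD-2728 library 2 or 3. In all, 2493 genes were higher than with vehicle and 2290 lower, 966 and 442 of them at least 2-fold. With 1 library left out, 2081 to 3110 were higher and 1676 to 2977 lower, and with library size only 35.9% of called genes were higher in place of 52.1%. Of the 984 genes raised at least 2-fold by IL1beta, 898 were called higher here, and of the 480 lowered, 363 were called lower. Independent lists would give 144 and 64.7. Counts simulated at the vehicle mean for all 3 groups gave 0 and 0 in each of 20 draws, a chance value without an effect that does not measure what shared vehicle libraries add. With the fold changes of called genes given to random genes of similar mean, 20 draws gave 125 (98 to 141) and 73.9 (64 to 85). These draws used the vehicle libraries in both comparisons, as the data do. The observed 898 and 363 lay above their highest values of 141 and 85. This argues against shared vehicle libraries as the main source of the excess. The draws had fewer called genes than the data (2173 higher and 1896 lower on average), so the exact part that sharing adds is not known.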

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

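The removal of the exon length trend, its partner fit, the fit without mitochondrially encoded genes and the mean CPM scale were chosen after the data were seen, and all other alternatives were planned and run. Over the main counts, shares and list counts, 363 of 436 alternatives were the same, 22 weaker, 14 stronger and 37 moved. Counts of list members were the same in 3062 of 3450 alternatives, weaker in 242 and stronger in 146. For named genes the numbers were 15985 the same, 486 weaker and 271 stronger of 16742, with 0 reversed. A count is taken as the same within 1.5 times, a share inside its Wilson interval and a part left within its SD over the CDD-2728 libraries. For the main results no class for a reversal was defined. Where no cause is given, the cause was not tested.

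Scaling by library size only gave 3605 lower genes for IL1beta against vehicle and 3488 for CDD-2728 with IL1beta against vehicle, and a median part of the IL1beta fall left with CDD-2728 of 82.1%. This scaling moved the median of all genes by construction. DESeq2 size factors moved none of these results.

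For CDD-2728 against IL1beta, no low-count filter gave 271 higher genes (36 at least 2-fold), a share of IL1beta-raised genes lowered of 13.0% and a fall left of 79.6%. At least 1 CPM in 3 libraries gave 13.6% and 83.2%. DESeq2 gave 294 higher (36 at least 2-fold), 13.6% and 79.6%, and limma-voom 13.0%. Only the 2 groups compared gave 111 higher and 192 lower, with fewer libraries in the fit. A block for replicate number gave 288 higher (28 at least 2-fold), 465 lower and 14.2%. It called all 477 genes of the unblocked fit, and the extracellular matrix and contractile list (camera adjusted p = 0.039). The labels state no pairing. Over all tested genes, deviations of same-numbered libraries from their group means correlated at -0.0182 to 0.0596 (0 of 9 pairs over 0.1). Over genes of at least 10 CPM this was -0.0555 to 0.454 (7 of 9 over 0.1), and CDD-2728 library 2 correlated better with IL1beta library 3 (0.323) than with IL1beta library 2 (0.144). The block was not used, since over all tested genes no pair was over 0.1. All 3 pairs of IL1beta and CDD-2728 libraries were over 0.1 at 10 CPM (0.454, 0.144 and 0.358), so a factor shared by replicate number is not excluded for this comparison.

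An adjusted p under 0.01 gave, by its stricter construction, 1485 lower genes for IL1beta against vehicle, 78 higher (8 at least 2-fold) and 160 lower for CDD-2728 against IL1beta, and 1456 lower for CDD-2728 with IL1beta against vehicle. The shares were 7.85% and 5.21% and the fall left was 84.5%. A test against a fold of 1.2 gave 1616 higher and 1172 lower, 33 higher (9 at least 2-fold) and 76 lower, and 1539 higher and 1132 lower for these comparisons.

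Camera with an estimated correlation called 6 lists for CDD-2728 against IL1beta. The fry test, which does not compare a list with other genes, called 23 for IL1beta against vehicle and 20 for CDD-2728 with IL1beta against vehicle. With a minimum IL1beta change of 2 on the log2 scale, the share of lowered genes raised was 11.1% and the fall left 70.6%. With no minimum the shares were 7.84% and 3.38%, the rise left 91.1% and the fall left 87.3%. With the length trend removed the share was 13.2% and the fall left 79.6%. On the mean CPM scale the rise left was 92.7% and the fall left 89.0%.

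With each library left out in turn, CDD-2728 against IL1beta had 86 to 616 higher genes, 12 to 38 at least 2-fold higher and 139 to 953 lower. The share of IL1beta-raised genes lowered was 6.18% to 15.4%, the share of lowered genes raised 5.0% to 12.7% and the fall left 78.3% to 82.1%. The highest of these counts and of the 2 shares were those without CDD-2728 library 1, and the lowest those without an IL1beta library. The fall left was highest without CDD-2728 library 2 and lowest without IL1beta library 2.

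At 33402733 to 47721630 counts per library, genes with few counts limit the folds: a gene absent from all vehicle libraries has only a lower bound.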

Other observations

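The tests of exon length, of the size of the CDD-2728 response and of single libraries were chosen after the results were seen, while those of depth, of 3' UTR motifs and of other splits of the libraries were planned. Among regulators of decidualization, the differentiation of endometrial stroma, 8 of 19 were higher with IL1beta, 7 lower and 4 not called (8 and 7 adjusted over the list alone; camera adjusted p = 0.28; median log2 0.09, mean 0.02, direction by camera lower). The homeobox gene HOXA10 changed by -1.27 (SE 0.11) and SOX4 by -1.67 (SE 0.078), whereas CEBPD rose by 1.81 (SE 0.12), BMP2 by 1.80 (SE 0.059) and IL15 by 1.68 (SE 0.12). With CDD-2728 added, 2 were higher, 1 lower and 16 not called (4 and 1 adjusted over the list alone; camera adjusted p = 0.57), and BMP2 went from 319 ± 4.10 to 189 ± 7.21 CPM (log2 -0.76, SE 0.058). Without IL1beta library 2, 1 was higher, and without CDD-2728 library 1, 6. Among steroid synthesis and hormone receptor genes 4 were higher with IL1beta and 11 not called (4 and 0 adjusted over the list alone; camera adjusted p = 0.31; median log2 -0.07, mean 0.31), led by HSD11B1, which regenerates cortisol, from 4.20 ± 1.00 to 47.8 ± 1.27 CPM (log2 3.50, SE 0.15). The glucocorticoid receptor NR3C1 rose by 0.96 (SE 0.082). With CDD-2728 added, 0 of these 15 genes were called by edgeR (1 higher adjusted over the list alone; camera adjusted p = 0.96), 1 by DESeq2 and 0 by limma-voom, and 4 had an unadjusted p under 0.05. When CDD-2728 library 1 was left out, 1 was higher and 1 lower. Cell cycle genes had 1 higher and 3 lower of 25 with IL1beta (0 and 3 adjusted over the list alone; camera adjusted p = 0.44), with CCND1 at log2 -0.57 (SE 0.060). The number lower was 1 without IL1beta library 3 and 6 without CDD-2728 library 1. The higher gene, AURKB, lost its call without vehicle library 1 (adjusted p = 0.17) or 2 (0.12) or IL1beta library 1 (0.054), 2 (0.22) or 3 (0.062), and 2 were higher without vehicle library 3 or CDD-2728 library 1. With CDD-2728 added, 0 were called by edgeR, DESeq2 or limma-voom and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.16, or 0.036 without CDD-2728 library 3), and without CDD-2728 library 1, 2 were higher.

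Stromal fibroblast markers had a median of 238 CPM with vehicle, 230 with IL1beta and 282 with CDD-2728 (with IL1beta 2 higher, 4 lower and 5 not called; 2 and 5 adjusted over the list alone; camera adjusted p = 0.28). In that comparison 1 was higher without any 1 vehicle library or IL1beta library 1 or 2, and 7 were lower without CDD-2728 library 1. With CDD-2728 added, 2 were higher and 9 not called (4 and 0 adjusted over the list alone; camera adjusted p = 8.9e-04, or 0.063 with an estimated correlation), with PDGFRA from 223 ± 6.06 to 311 ± 24.6 CPM (log2 0.48, SE 0.066). Without CDD-2728 library 1, 7 were higher and 1 lower, and without any 1 of the other libraries 1 was higher. Epithelial markers had medians of 31.8, 22.7 and 23.1 CPM (with IL1beta 2 higher, 4 lower and 1 not called; 2 and 4 adjusted over the list alone; camera adjusted p = 0.21; median log2 -0.36, mean 0.75), with KRT18, which has many pseudogenes, at log2 -0.94 (SE 0.053). Without vehicle library 1 or 2, or IL1beta library 2 or 3, 1 was higher. For CDD-2728 against IL1beta 1 was higher and 6 not called (3 and 0 adjusted over the list alone), but 0 without vehicle library 1 or 2, any 1 IL1beta library or CDD-2728 library 2, and 3 without CDD-2728 library 1. The camera adjusted p was 0.019, or 0.062 without IL1beta library 3 and 0.083 with an estimated correlation. Medians were lower for endothelial (3.02, 1.13 and 0.839 CPM), mesothelial (2.81, 2.22 and 2.07 CPM), granulosa and ovarian stromal (1.2, 1.29 and 1.2 CPM) and leukocyte markers (0.972, 0.721 and 1.07 CPM). Single members were higher, with TEK at 29.2, EGFL7 at 17.9, WT1 at 24.6 and CALB2 at 65.3 CPM in vehicle. With IL1beta the first of these had 0 higher, 2 lower and 3 not called (camera adjusted p = 0.21), the mesothelial list 2 higher and 4 not called (0.64) and the granulosa list 1 lower and 4 not called (0.052, but 0.042 without vehicle library 1 or 2 and 0.047 without IL1beta library 2). In each comparison 0 of 4 leukocyte markers were called by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05, and the list was too short for camera. For CDD-2728 against IL1beta 0 of 5 endothelial and 0 of 5 granulosa markers were called by these tools (1 each at an unadjusted p under 0.05; camera adjusted p = 0.99 and 0.63). Of the mesothelial markers 1 was lower (camera adjusted p = 0.16), WT1, whose call (log2 -0.35) was lost without vehicle library 2 (adjusted p = 0.063), any 1 IL1beta library (0.075 to 0.15) or CDD-2728 library 2 (0.081) or 3 (0.10). For CDD-2728 with IL1beta against vehicle, the granulosa and ovarian stromal list had 0 higher, 1 lower and 4 not called (0 and 2 adjusted over the list alone). Its camera adjusted p was 0.031 (lower), or 0.062 without CDD-2728 library 1, 0.059 without CDD-2728 library 3 and 0.098 with an estimated correlation. FOXL2, an ovarian stromal gene, was well expressed in vehicle and changed by -1.66 (SE 0.070) with IL1beta, from 125 to 39.6 CPM. Smooth muscle and pericyte markers had medians of 70.3, 43.2 and 58.2 CPM (with IL1beta 1 higher, 3 lower and 5 not called; 1 and 4 adjusted over the list alone; camera adjusted p = 0.18). For CDD-2728 against IL1beta 2 were higher and 7 not called (3 and 2 adjusted over the list alone), and 1 was higher without vehicle library 2, any 1 IL1beta library or CDD-2728 library 3. Their camera adjusted p was 0.021, or 0.062 without IL1beta library 3 and 0.083 with an estimated correlation.

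Library 1 of the CDD-2728 group stood apart from libraries 2 and 3. The squared log2 difference was 3.08 times the highest of the other same-group pairs, and still 2.54 times with each library's trend on exon length removed, which argues against that trend as the whole cause (Spearman's rho of the library's deviation with length was 0.44 across 9078 genes). At equal depth the chi-square per gene was 3.62 times the highest of the other pairs, which argues against lower depth. Whether the inhibitor response itself differed stays open, since the ratio of 1.01 over called genes is void (those genes were picked for agreement) and the ratio over genes called without the library was 0.390, but 0.852 over the top 300 genes. Over genes of at least 10 CPM, its deviation from its group mean correlated at 0.381 with that of vehicle library 1 and 0.454 with that of IL1beta library 1. With the other vehicle and IL1beta libraries the values were -0.439 to 0.0845. A factor shared by replicate number 1 was not tested as a cause. No biological explanation was tested beyond this, since the labels give none.

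Higher interferon genes with CDD-2728 may reflect the inhibitor or single libraries. With the exon length trend removed, the list's median log2 fold change was 95.02% of that without removal, which argues against the trend. The lowest median without 1 library was 81.4% of that with all. Its bootstrap 95% interval of 46.4% to 95.7% (10000 draws) resampled genes of the list and not libraries, so it cannot settle the role of 1 library. With each library left out in turn, the list's median stayed between 0.32 and 0.55, against 0.40 with all libraries. This argues against 1 library as the whole source of the higher median. How much 1 library adds to its size stays open, and an effect of the inhibitor is untested beyond this. The medians for CDD-2728 libraries 1, 2 and 3 were 0.35, 0.41 and 0.56, and 3 members were called without IL1beta library 1 against 10 with all libraries (5 without IL1beta library 2, 6 without CDD-2728 library 3, 16 without CDD-2728 library 1).

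A hypothesis was that the IL1beta-raised genes lowered by CDD-2728 may carry more ATTTA motifs, which mark unstable messenger RNA, in their 3' UTRs. The 103 lowered genes with a 3' UTR had 2.76 ± 2.38 per kb and 588 genes not called had 2.59 ± 2.64 (SD). The difference was 0.170 per kb (permutation p = 0.77, two-sided, 100000 permutations within 5 bins of the IL1beta fold change). The test is void, since only 69.6% of the genes not called had an annotated 3' UTR, against 97.2% of the lowered genes.

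The real split of the libraries gave the highest value (1 of 10 splits) for each of the 17 results below, but 10 splits are too few for a share under 0.05. Each other split mixes both treatments within a group, which widens the spread there. Low gene counts in those splits thus follow from their construction and do not measure chance. For IL1beta against vehicle, 2677 higher and 2309 lower genes (984 and 480 at least 2-fold) stood against at most 0 in another split, and 13 lists against 6. For CDD-2728 against IL1beta, 176 higher and 301 lower genes stood against at most 2 and 2, 18 and 28 at least 2-fold against 0, and 12 lists against 6. The shares of 10.8% and 8.13% stood against 0.0985% and 0%. For CDD-2728 with IL1beta against vehicle, 2493 higher and 2290 lower genes (966 and 442 at least 2-fold) stood against 0, and 12 lists against 5.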
